A study of Mus musculus with 6 samples.

How the data were processed

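Total RNA was prepared from ear epidermis that had been incubated either with dispase, which frees the whole epidermal sheet, or with exfoliative toxin A, which frees the upper layers, per the labels' protocols. Libraries were made with a directional (strand-keeping) kit and sequenced as paired reads of 25 bp on an Illumina HiSeq 2000 instrument, per the labels. The submitters' processing notes name Salmon and Bowtie2 and the mouse build mm9, without versions or roles; the annotation was not given in the sources used here beyond the RefSeq transcript accessions that name the transcripts. The authors deposited 1 table of TPM for 37903 transcripts, with a gene symbol for all but 7951 of them. TPM divides estimated reads by transcript length and scales each library to a total of 1000000, so depth is lost and no counting interval could be given. Values of 0 were spread unevenly: among genes with a mean of at least 10 TPM, 221 were listed at 0 in ETA sheet replicate 2, against 12 to 36 in the other 5 libraries.

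Columns were given to samples by the library number, which stands in both the column name and 1 sample title. In 4 of the 6 columns the sheet name beside that number differs from the title, and the group was taken from the title. The values had been looked at before this choice was written down, so the grouping by header names is reported as an alternative.

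TPM was summed over the transcripts of each of 20522 gene symbols, of which 20311 matched the reference gene tables (GRCm38). Transcripts without a symbol, which held 3.57% to 6.65% of the TPM per library, stayed out of the tests; 7786 of them could be named by accession for an alternative and for the closing part. Genes with a mean of at least 1 TPM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a trended empirical Bayes fit of ETA sheet minus epidermal sheet and Benjamini-Hochberg adjustment. Log2 fold changes are on this scale, which understates the change of low genes; folds are ratios of mean TPM. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. A list needed at least 3 tested members; 33 of 34 lists had them, and the mitochondrially encoded genes were not analysed here. Immediate early genes, ion channels and differentiation transcription factors had a median slightly below that of all genes and a camera direction above it, and heat shock genes the reverse; none of the 4 passed the test. Sums of other-cell-type lists and shares of TPM were compared with two-sided exact permutation tests, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

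The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, and the giving of columns to samples was not. The rule takes, per direction, the 10 genes with the largest log2 fold change among those called, with at least 10 TPM in the higher group and no overlap between groups, passing over predicted genes, small RNAs and pseudogenes. It adds from each list the most abundant member and up to 2 called members per direction, and a set of 24 well-known epidermal genes. Krt15, Sprr2a1, Sprr4, Cytl1 and the families with their genes in the closing part were chosen after their values were seen. One result under this rule is not reported here. The alternatives were other pseudocounts, filters and scalings, a replicate block, no variance trend, library weights, the largest transcript in place of the sum, a test against a 2-fold change, and leaving out each library. The library weights were 5.37 for ETA sheet replicate 3 and 0.370 and 0.341 for replicates 1 and 2. Results with library weights therefore rest mostly on 1 ETA sheet library. Groups by header names, names filled in by accession, and leaving out ETA sheet replicates 1 and 2 together were added after seeing the data. No positions are given, since the reference annotation used for names, lengths and GC content is of another build than mm9.

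The fit was tested on simulated data for the comparison of ETA with epidermal sheets, with 11683 genes at their measured means and spreads, of which 200 were changed. Of 67 genes changed 1.5-fold it called 1, of 67 changed 2-fold 7, and of 66 changed 4-fold 34, all in the planted direction; of 11483 unchanged genes 3 were called. A planted list was called and 0 of 29 unmoved lists were. The simulated genes varied independently and had no common shift. In the measured data 8613 genes were called, and the estimated correlation within the ribosomal protein list was 0.882. The simulation therefore cannot show how the list test behaves when members move together, nor the share of true changes found in the measured comparison.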

Results

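The epidermis of the mouse ear was profiled by RNA sequencing in 6 libraries from female C57BL6/N mice of 8 weeks. In 3 libraries the RNA came from whole epidermal sheets, which were lifted from the dermis with dispase and hold every living layer from the basal to the granular cells. In the other 3 the RNA came from ETA sheets, the upper layers peeled off with exfoliative toxin A, a staphylococcal protease that cleaves desmoglein 1; per the labels these sheets hold the granular cells called SG1 and SG2. The deposited values are TPM, length-scaled shares of the reads that sum to 1000000 in each library, and keep no depth, so the precision of single libraries is unknown. The solution used for isolation differed between the groups, so layer and solution cannot be told apart. The labels do not say that the 3 sheets of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. For 4 of the 6 libraries the sheet name in the column header differed from that in the sample title with the same library number, and groups followed the titles. With the header names as groups limma called 0 genes, against 87 at an unadjusted p under 0.05.

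The comparison of ETA sheets with whole epidermal sheets asks which transcripts differ in level between the peeled upper layers and the whole epidermis. Transcripts of the cornified envelope, the protein shell of the dead surface cells, were far more abundant in ETA sheets, and the basal keratins Krt5 and Krt14 were nearly lost. The cornified envelope lists together took 32.2 ± 3.94% of all TPM in ETA sheets and 3.03 ± 0.278% in epidermal sheets (SD, n = 3 each). Cytosolic ribosomal protein genes moved the other way, with 7.97%, 5.10% and 5.29% in the ETA sheet replicates and 24.1 ± 1.76% in epidermal sheets. The 10 most abundant genes held 28.8 ± 2.79% of the TPM in ETA sheets against 10.6 ± 0.182%, and the 100 most abundant 57.1 ± 2.95% against 40.7 ± 1.90%. In all 4 of these shares the 3 libraries of one group lay beyond the 3 of the other, for which the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allow. Of 11683 genes tested with limma, 1181 were higher and 7432 lower in ETA sheets at a Benjamini-Hochberg adjusted p under 0.05, and 3070 were not called. Changes of at least 2-fold were called for 973 higher and 6762 lower genes. A TPM is a share of a fixed total, and the median log2 fold change of all tested genes was -1.34. The balance of calls therefore depended on the scaling. Trimmed-mean scaling gave 2685 higher and 3310 lower genes, so that 55.2% of calls were lower in place of 86.3%. Median centring gave 3405 higher and 2202 lower genes (39.3% lower). The median log2 fold change of all tested genes was then 0.157, so a smaller positive change in this setting lies below the median gene. All 1181 genes called higher were also called higher after median centring, whereas 2202 of the 7432 lower calls stayed lower and 469 became higher. Median centring raised every log2 fold change by the same amount, also for genes with very low TPM. The rises could therefore hardly lose their calls, and only the falls were put to a test. List medians are therefore given relative to the median of all genes below, unless named as deposited, and a fall is stated as kept only where it held after median centring.

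The basal layer, which anchors the epidermis and holds its dividing cells, was depleted in ETA sheets. All 20 tested basal keratinocyte genes fell, 16 of them also after median centring, with a median 2.54 log2 units below that of all genes (camera adjusted p = 3.27e-05; adjusted p = 0.329 with an estimated correlation). Krt5, a basal keratin, had 6177 ± 205 TPM in epidermal sheets and 48.6 ± 14.1 in ETA sheets (SD, n = 3; log2 fold change -7.00 ± 0.23 SE, limma adjusted p = 3.96e-06). Its partner Krt14 fell from 8698 ± 997 to 109 ± 26.1 TPM. Col17a1 and Itga6, components of the hemidesmosome, fell 75.4-fold and 48.6-fold, and Trp63, a transcription factor of basal keratinocytes, fell 14.5-fold. These falls held after median centring, with log2 changes of -5.51 for Krt5, -4.83 for Krt14, -4.65 for Col17a1, -3.57 for Itga6 and -2.37 for Trp63. Among 30 cell cycle genes, 27 fell and 0 rose (28 fell when adjusted over the list alone), and 21 fell after median centring. Their median lay 1.85 log2 units below that of all genes (camera adjusted p = 6.85e-05; adjusted p = 0.204 with an estimated correlation). Mki67, a marker of proliferating cells, had 19.9 ± 3.78 TPM in epidermal sheets and 0.134 ± 0.150 in ETA sheets, and Top2a, a topoisomerase of dividing cells, had 30.5 ± 2.92 and 0.205 ± 0.210.

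**Figure D1:**
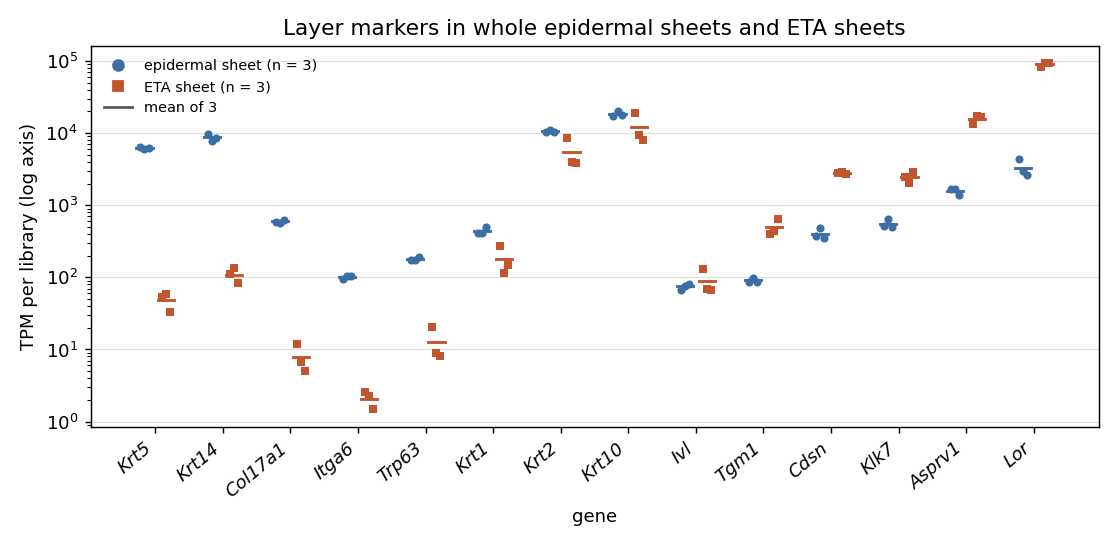
TPM per library on a log axis for 14 layer markers in epidermal sheets (circles, n = 3) and ETA sheets (squares, n = 3), with a bar at each mean. Krt5 and Krt14 lie near 6177 and 8698 TPM in epidermal sheets and near 48.6 and 109 in ETA sheets, whereas Lor rises from 3331 to 89898; Krt1, Krt2 and Krt10 are lower in mean TPM as deposited but not after median centring.

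Genes of terminal differentiation rose. In the late cornified envelope and small proline-rich families 29 of 33 tested members rose and 4 fell, with a median log2 fold change as deposited of 3.67 (camera adjusted p = 1.27e-29; adjusted p = 0.153 with an estimated correlation). Lce1a1 rose 16.4-fold to 28104 ± 3925 TPM. The 4 that fell were Sprr2a1, Sprr2a2, Sprr2a3 and Sprr4, and after median centring 0 of the 33 were called lower. Sprr2a3 lost its call without ETA sheet replicate 3 (log2 -3.10), and Sprr2a2 without epidermal sheet replicate 1 or 3 (log2 -1.21 and -2.18) or ETA sheet replicate 1 or 3 (log2 -2.14 and -1.83). Members of these families share near-identical sequence, and reads of 25 bp could be divided between them, so single-member values are uncertain. In the list of cornified envelope and filaggrin-type proteins 11 of 19 rose and 3 fell (median 2.52 above all genes, camera adjusted p = 4.44e-11; adjusted p = 0.0326 with an estimated correlation). Lor, the main envelope protein, had 3331 ± 935 TPM in epidermal sheets and 89898 ± 5609.9 in ETA sheets (SD, n = 3; log2 fold change 4.79 ± 0.22 SE, limma adjusted p = 6.32e-06). Kprp rose 24.0-fold, Cdsn, which encodes corneodesmosin, 6.97-fold, and Tgm1, a transglutaminase that cross-links the envelope, 5.45-fold. Another transglutaminase, Tgm3, fell 8.49-fold and also after median centring (log2 -1.47), while Tgm5 fell as deposited with the sign turned under median centring (log2 0.34, not called). Ivl, the envelope protein involucrin, was not called at 74.9 ± 7.16 against 89.7 ± 36.8 TPM (adjusted p = 0.549), but was called higher after median centring (log2 1.68). Filaggrin was not analysed here.

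Many enzymes of the barrier rose, and others fell. Of 29 epidermal proteases and protease inhibitors 18 rose and 6 fell, with 25 higher and 1 lower after median centring (median 2.62 above all genes, camera adjusted p = 9.46e-14; adjusted p = 0.0326 with an estimated correlation). Asprv1, the aspartic protease that processes profilaggrin, rose from 1568 ± 165 to 15867 ± 2056 TPM (log2 fold change 3.33 ± 0.17 SE, limma adjusted p = 7.40e-06). The kallikreins, serine proteases of desquamation, rose 2.67-fold for Klk5, 4.46-fold for Klk7 and 14.3-fold for Klk9, and Casp14, a caspase of cornification, rose 5.48-fold. Capn1, a calpain, fell 10.3-fold and also after median centring (log2 -1.77). Of 33 genes of barrier lipid synthesis and transport 15 rose and 8 fell, with 24 higher and 3 lower after median centring (median 1.82 above all genes, camera adjusted p = 2.82e-08; adjusted p = 0.328 with an estimated correlation). The lipoxygenases Alox12b and Aloxe3 rose 4.70-fold and 8.30-fold, the lipid transporter Abca12 rose 6.60-fold and the lipase Lipn 13.2-fold. In the same list Fa2h, a fatty acid hydroxylase, fell 19.1-fold and Cers4, a ceramide synthase, 14.4-fold, both also after median centring.

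Spinous, junctional and regulatory genes divided. Of 16 spinous genes 3 rose and 7 fell (camera adjusted p = 0.196), whereas 9 were higher and 2 lower after median centring, where the list lay above other genes (camera adjusted p = 0.0463; as deposited, adjusted p = 0.827 with an estimated correlation). Krtdap and Sbsn, secreted keratinocyte proteins, rose 1.78-fold and 3.35-fold, whereas Mt4, a metallothionein, fell 15.9-fold. The suprabasal keratins had no direction that held under every scaling. Krt10 had 18546 ± 1502 TPM in epidermal and 12209.9 ± 6051 in ETA sheets (adjusted p = 0.0640). It was called lower without ETA sheet replicate 1 (log2 -1.09), with the replicate block (log2 -0.71) and with library weights (log2 -1.11). Those weights rest mostly on ETA sheet replicate 3. After median centring Krt10 was called higher (log2 0.79). Krt1 and Krt2 fell 2.48-fold and 1.95-fold as deposited and were not called after median centring (log2 0.10 and 0.42). Of 14 desmosome genes 2 rose and 10 fell (camera adjusted p = 0.937), with 5 higher and 3 lower after median centring. Dsg3 and Dsc3, desmosomal cadherins of the lower layers, fell 33.5-fold and 7.33-fold and also after median centring, while Dsg1a, the target of the toxin, fell 2.30-fold as deposited only. Of 21 tight junction genes 4 rose and 9 fell (camera adjusted p = 0.207), with 10 higher and 3 lower after median centring. Cgn, which encodes cingulin, rose 3.30-fold and Marveld2, which encodes tricellulin, fell (log2 -3.14). Cldn1 had 187 ± 36.9 and 131 ± 34.7 TPM, was not called as deposited (adjusted p = 0.0814) and was called higher after median centring (log2 0.97). It was called lower without epidermal sheet replicate 1 (log2 -0.69) or ETA sheet replicate 1 (log2 -0.72). Cldn4 was not called at 223 ± 48.0 and 322 ± 86.8 TPM (adjusted p = 0.103), but was called higher after median centring (log2 2.00) and without ETA sheet replicate 2 (log2 0.76). Of 28 differentiation transcription factors 3 rose and 16 fell (camera adjusted p = 0.788), with 12 higher and 5 lower after median centring. The repressor Prdm1 rose 10.9-fold and Ehf 3.77-fold, while Grhl2 fell 14.5-fold and Tfap2c 7.51-fold. Klf4 was not called at 894 ± 24.2 and 1011 ± 218 TPM (adjusted p = 0.456), but was called higher after median centring (log2 1.65). Of 35 genes of ion channels, calcium handling and pH transport 6 rose and 18 fell (camera adjusted p = 0.497), with 14 higher and 7 lower after median centring. The carbonic anhydrase Car6 rose 4.52-fold and the sodium channel subunit Scnn1b from 1.18 ± 1.17 to 9.84 ± 2.75 TPM, while the water and glycerol channel Aqp3 fell 8.65-fold. The cation channel Trpv3 had 9.47 ± 5.96 TPM in epidermal and 8.26 ± 2.10 in ETA sheets. It was not called as deposited (log2 fold change 0.01 ± 0.49 SE, adjusted p = 0.987), but was called higher after median centring (limma adjusted p = 0.0361).

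Ribosomal protein and oxidative phosphorylation genes fell relative to other genes. All 76 ribosomal protein genes fell, 52 of them also after median centring (median 0.75 below all genes, camera adjusted p = 4.63e-10; adjusted p = 0.566 with an estimated correlation). Rplp1, the most abundant of them, had 13965 ± 1049 TPM in epidermal and 3014 ± 1082 in ETA sheets. Of 71 nuclear genes of oxidative phosphorylation 69 fell and 1 rose (median 0.59 below all genes, camera adjusted p = 7.83e-07; adjusted p = 0.566 with an estimated correlation), and after median centring 28 were lower and 6 higher. The exception was Ndufa4, which rose 2.39-fold, while Sdhd, a subunit of succinate dehydrogenase, fell 17.7-fold. Of 18 glycolysis genes 14 fell and 0 rose (camera adjusted p = 0.0470; adjusted p = 0.603 with an estimated correlation). That list call was lost without epidermal sheet replicate 1 (adjusted p = 0.0512) or replicate 2 (adjusted p = 0.0565), with trimmed-mean scaling (adjusted p = 0.0714), rescaled without the 100 most abundant genes (adjusted p = 0.0751) and with a filter of 5 TPM (adjusted p = 0.0807). After median centring 8 of the 18 were lower and 3 higher. Gapdh fell 7.78-fold and also after median centring (log2 -1.53). Of 22 cholesterol synthesis genes 2 rose and 10 fell (camera adjusted p = 0.207), but after median centring 14 were higher and 1 lower. The list passed as higher after median centring (camera adjusted p = 0.00239), with trimmed-mean scaling (adjusted p = 0.000446) and rescaled without the 100 most abundant genes (adjusted p = 0.0274); as deposited, adjusted p = 0.843 with an estimated correlation. Dhcr7, a reductase of the pathway, rose 2.45-fold.

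Autophagy genes and nucleases of cornification included some of the clear rises. Of 25 autophagy genes 10 rose and 10 fell, with 16 higher and 1 lower after median centring (median 1.21 above all genes, camera adjusted p = 3.01e-05; adjusted p = 0.0689 with an estimated correlation). Gabarapl2, which is coupled to autophagosome membranes, rose 9.23-fold to 2533 ± 561 TPM and Atg9b 13.2-fold, while Tfeb, a transcription factor for lysosomal genes, fell 6.49-fold. Of 27 genes of cell death and nucleic acid degradation 5 rose and 13 fell (camera adjusted p = 0.148), with 10 higher and 4 lower after median centring. The DNA-degrading enzymes Trex2 and Dnase1l2 rose 10.7-fold and 7.37-fold, and the ribonuclease Rnase4 fell (log2 -3.62).

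**Figure D2:**
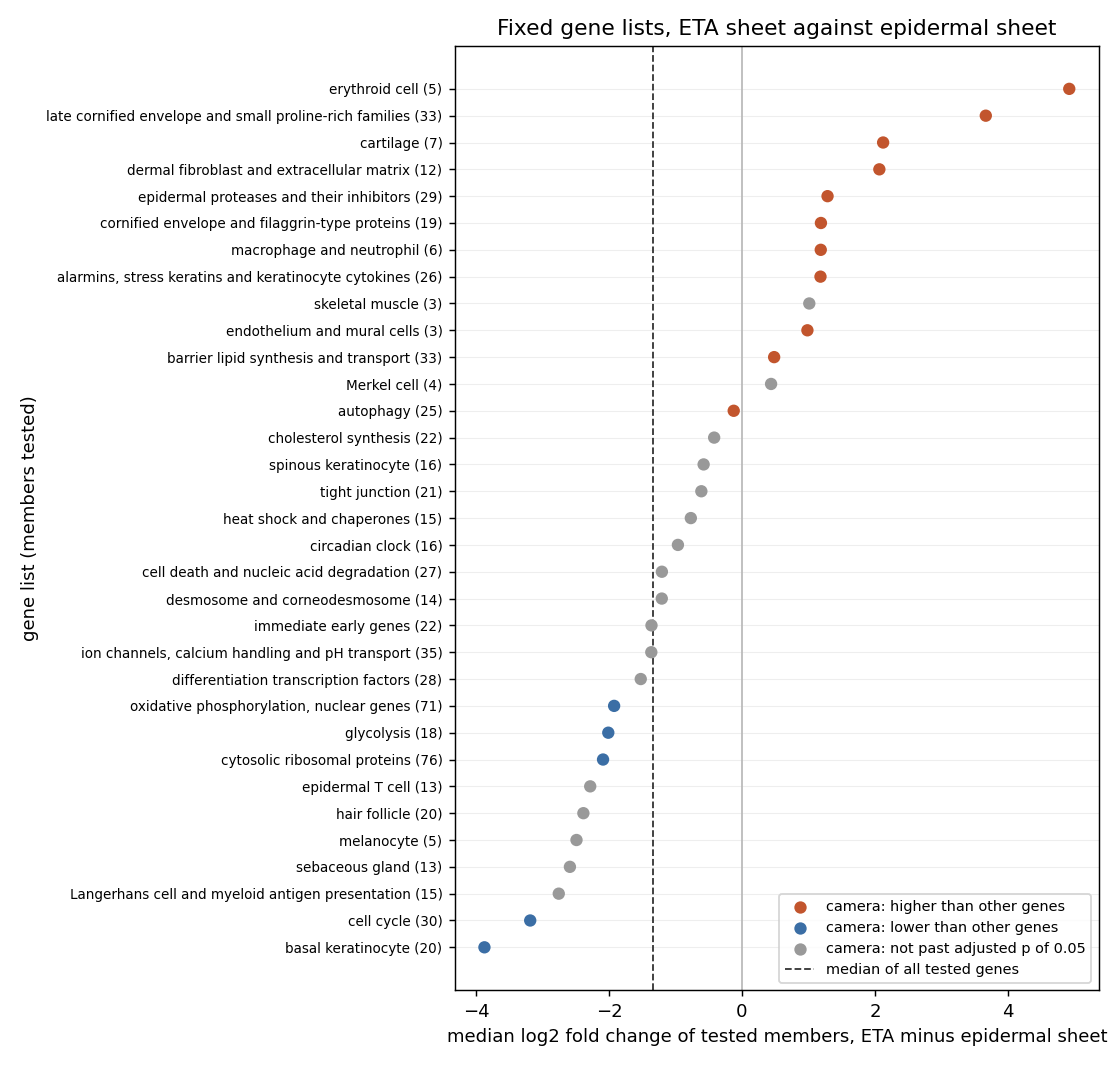
Median log2 fold change of the tested members of each of 33 gene lists, ETA minus epidermal sheet as deposited (horizontal axis, log2 units), with the number tested in brackets. The dashed line marks the median of all tested genes at -1.34, and colours give the camera result at the preset correlation, with 11 lists above and 5 below other genes; 2 lists stay above and 0 below with an estimated correlation.

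Of 4 lists of genes that respond to handling, injury or time of day, only the alarmins passed the camera test. Of 22 immediate early genes 4 rose and 14 fell (camera adjusted p = 0.759), with 9 higher and 6 lower after median centring. Fos and Atf3 had 1693 ± 23.7 and 801 ± 91.3 TPM in epidermal sheets and 174 ± 75.5 and 65.6 ± 22.4 in ETA sheets, falls that held after median centring (log2 -1.89 and -2.14), while Ier5 rose 7.48-fold. Junb fell slightly as deposited (log2 -0.52) and was called higher after median centring (log2 0.97). Of 15 heat shock and chaperone genes 1 rose and 11 fell (camera adjusted p = 0.497), with 8 higher and 4 lower after median centring. Hspd1, a mitochondrial chaperonin, fell from 92.1 ± 4.16 to 3.39 ± 4.19 TPM (log2 -5.73 to -4.14 with 1 library left out). Of 26 alarmins, stress keratins and keratinocyte cytokines 9 rose (8 when adjusted over the list alone) and 5 fell, with 14 higher and 2 lower after median centring (median 2.52 above all genes, camera adjusted p = 5.96e-07; adjusted p = 0.0689 with an estimated correlation). That median was 1.21 without ETA sheet replicate 1. The cytokine Il1a rose 15.4-fold and its relative Il1f8 5.88-fold, the defensin Defb14 rose 11.1-fold, and the alarmin Il33 fell 41.5-fold. Of 16 clock genes 2 rose (1 when adjusted over the list alone) and 9 fell (camera adjusted p = 0.759), with 6 higher and 1 lower after median centring; as deposited Cry2 rose 1.76-fold and Hlf fell 10.1-fold. For all other lists the counts adjusted over the list alone equal those given, except skeletal muscle with 0.

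Summed TPM of Langerhans cell, T cell, melanocyte, hair follicle and sebaceous gland genes was lower in every ETA sheet library than in any epidermal sheet library, and that of Merkel cell genes was not. The sums are shares as deposited. On the log2(TPM + 1) scale the median change of all tested genes was -1.34, a ratio of 0.396. That scale understates the change of low genes, so this ratio cannot be set directly against ratios of summed TPM. Antigen presentation genes of Langerhans cells, the dendritic cells of the epidermis, summed to 1550 ± 136 TPM in epidermal and 165 ± 82.4 in ETA sheets. Of 15 tested 10 fell, and after median centring 8 were lower and 2 higher. Cd74 fell 27.3-fold. T cell genes summed to 232 ± 20.4 and 17.2 ± 3.56 TPM and all 13 fell, 4 of them also after median centring. Melanocyte genes summed to 46.9 ± 0.829 and 4.72 ± 2.91 TPM and all 5 fell, 2 of them also after median centring. Hair follicle genes summed to 1452 ± 51.2 and 225 ± 78.4 TPM, with 13 of 20 falling, among them Krt79 11.4-fold and Postn 108-fold. After median centring 8 of the 20 were lower and 2 higher. Sebaceous gland genes summed to 2946 ± 628 and 1287 ± 143 TPM, with 8 of 13 falling and Dgat2, also an enzyme of other lipid-making cells, rising 2.08-fold. After median centring 6 of the 13 were lower and 3 higher. The sebaceous gland sum stood at 0.437 of its epidermal level, against 0.396 for the median tested gene, so it fell no further than that gene. Merkel cell genes summed to 12.8 ± 17.3 and 11.7 ± 7.53 TPM, with 0 of 4 called by limma and the groups overlapping (exact permutation p = 1). None of these lists passed the camera test as deposited, with adjusted p of 0.148 for Langerhans cells, 0.0740 for T cells, 0.137 for melanocytes, 0.148 for hair follicle, 0.542 for sebaceous gland and 0.125 for Merkel cells. After median centring lists passed it as lower for Langerhans cells (adjusted p = 0.00906), T cells (0.00906), melanocytes (0.0281) and hair follicle (0.0162). As deposited and with an estimated correlation, adjusted p = 0.566, 0.398, 0.334 and 0.654 for these 4 lists. T cells also passed with the replicate block (adjusted p = 0.0484), and hair follicle without epidermal sheet replicate 2 (adjusted p = 0.0166). Without the filter on low values lists passed as lower for Langerhans cells (adjusted p = 0.0229), T cells (0.0354) and hair follicle (0.0185). The Merkel cell list then passed as higher (adjusted p = 0.0454, against 0.566 with the filter and an estimated correlation). Unfiltered genes near 0 TPM can hardly fall, whereas the median log2 fold change of all genes was then -0.714, so this pass is weak evidence.

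Transcripts of dermal, cartilage and blood cells were higher in ETA sheets. Of 12 fibroblast and matrix genes 11 rose and 0 fell (camera adjusted p = 8.34e-11, and 0.0689 with an estimated correlation). Their sum was 46.1 ± 6.88 TPM in epidermal and 302 ± 165 in ETA sheets, with 300, 468 and 138 in replicates 1, 2 and 3. The cartilage sums given below were also higher in replicates 1 and 2 than in replicate 3. Bgn, the proteoglycan biglycan, rose from 4.34 ± 0.858 TPM to 72.0, 117 and 13.4 in ETA sheet replicates 1, 2 and 3 (log2 2.62 without ETA sheet replicate 2 and 4.13 without replicate 3). The collagen gene Col3a1, listed at 0 in 2 epidermal sheet libraries, rose from 0.387 ± 0.670 to 9.68 ± 1.61 TPM. Of 7 cartilage genes 5 rose (camera adjusted p = 2.64e-05; adjusted p = 0.334 with an estimated correlation), but their sums were 70.5, 85.3 and 4.94 TPM in ETA sheet replicates 1, 2 and 3 against 3.19 ± 1.57 in epidermal sheets. Without ETA sheet replicate 1 or 2 only 1 of the 7 was called, and without epidermal sheet replicate 2 or 3 only 2 of 8. All 5 erythroid genes rose (camera adjusted p = 1.37e-07; adjusted p = 0.217 with an estimated correlation). Their sum, nearly all globin, was 356 ± 113 TPM in epidermal sheets and 10009, 5195 and 24756 TPM in the ETA sheet replicates. Hbb-bs rose 52.1-fold and Hba-a1 37.3-fold. Macrophage and neutrophil genes summed to 15.5 ± 7.34 and 39.7 ± 21.3 TPM, with Lyz2 and Cxcr2 rising and C1qa falling among 6 tested (camera adjusted p = 0.0118; adjusted p = 0.328 with an estimated correlation). That list call was lost after median centring (adjusted p = 0.113), with trimmed-mean scaling (adjusted p = 0.172) and without ETA sheet replicate 1 (adjusted p = 0.0528). Endothelial genes summed to 7.94 ± 7.63 and 21.4 ± 7.85 TPM, with 0 of 3 called (camera adjusted p = 0.0388; adjusted p = 0.328 with an estimated correlation). That list call was lost after median centring (adjusted p = 0.195), with trimmed-mean scaling (adjusted p = 0.186), rescaled without the 100 most abundant genes (adjusted p = 0.0751) and without epidermal sheet replicate 1 (adjusted p = 0.0512) or replicate 2 (adjusted p = 0.0565). Skeletal muscle genes summed to 7.85 ± 5.54 and 13.3 ± 5.49 TPM, with 1 of 3 called as higher (camera adjusted p = 0.106). That gene, Tnnc2 of fast muscle, was listed at 0 in all epidermal sheets and lost its call without epidermal sheet replicate 1 (adjusted p = 0.0647), 2 (adjusted p = 0.0624) or 3 (adjusted p = 0.0572) or ETA sheet replicate 3 (adjusted p = 0.0515). The skeletal muscle list passed camera without epidermal sheet replicate 2 (adjusted p = 0.0164) or 3 (adjusted p = 0.0348) and without ETA sheet replicate 1 (adjusted p = 0.0417) or 3 (adjusted p = 0.0408). It also passed without the filter on low values (adjusted p = 0.00337). In that setting genes near 0 TPM can hardly fall, whereas the median log2 fold change of all genes was -0.714. A pass as higher is therefore weak evidence there. The list passed as well with library weights (adjusted p = 0.0430), which rest mostly on ETA sheet replicate 3. With all libraries and an estimated correlation, adjusted p = 0.329. Of the 12 summed lists, 8 had groups that did not overlap, each with a two-sided exact permutation p of 0.1, the smallest possible, and 0.15 after adjustment over the 12; chance gives such a separation in 10% of lists.

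**Figure D3:**
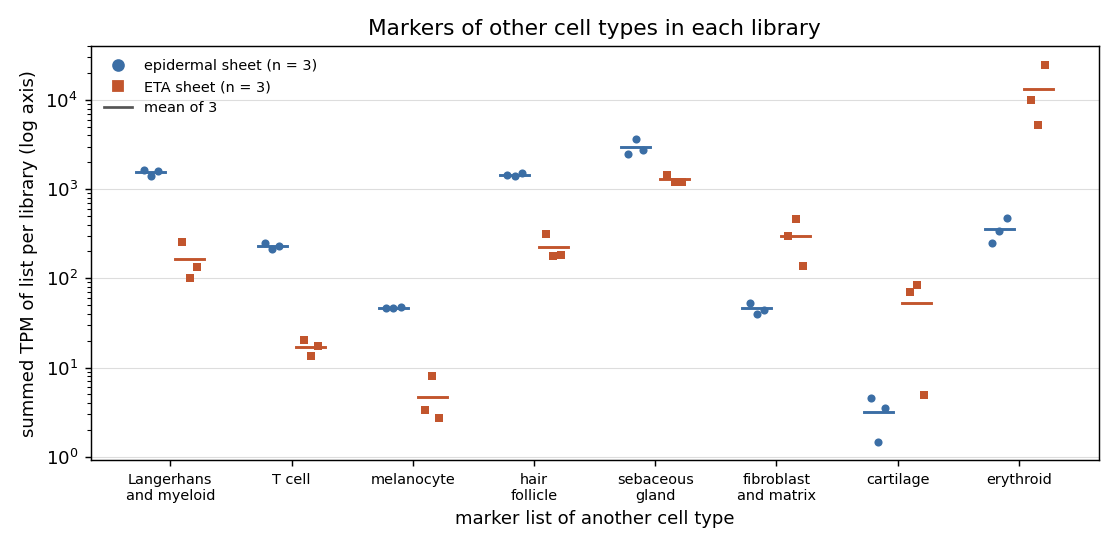
Summed TPM of the marker list of each of 8 other cell types per library, on a log axis, in epidermal sheets (circles, n = 3) and ETA sheets (squares, n = 3), with a bar at each mean. The 5 lists on the left are lower in ETA sheets as deposited, at 165 against 1550 TPM for Langerhans cells, and the 3 on the right are higher. Dgat2, also an enzyme of other lipid-making cells, held 684 of the 1287 TPM of the sebaceous gland sum in ETA sheets. Cartilage markers reach 70.5 and 85.3 TPM in ETA sheet replicates 1 and 2 but 4.94 in replicate 3.

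Among the genes with the largest changes outside these lists, several rose from a low level. Plcxd1, which encodes a phospholipase-like protein, rose from 21.4 ± 3.11 to 611 ± 144 TPM (log2 fold change 4.75 ± 0.22 SE, limma adjusted p = 6.32e-06) and Sybu from 0, 1.93 and 8.17 in the epidermal sheet replicates to 86.5 ± 13.7 (log2 4.07 to 5.66 with 1 library left out). Arhgap29 rose from 0.210, 20.4 and 0.282 TPM in the epidermal sheet replicates to 98.8 ± 19.0 (log2 4.23 to 6.31 with 1 library left out). Spink7, a protease inhibitor, had 74.4, 790.0 and 95.4 TPM in the ETA sheet replicates against 4.21 ± 7.29 in epidermal sheets. Pcp2 was listed at 0 in all 3 epidermal sheet libraries and at 32.5, 26.6 and 32.5 TPM in ETA sheets. Map2k2, a kinase of most cells, was listed at or near 0 in epidermal sheets and at 53.0, 14.7 and 33.9 TPM in ETA sheets, but its log2 fold change was 0.41 and not called (adjusted p = 0.0663) once transcripts listed without a gene name were added by accession. The largest falls outside the basal list included Clca3a2 from 390.0 ± 59.6 to 4.54 ± 2.32 TPM, Fcgbp from 242 ± 33.3 to 2.43 ± 0.258 and the Notch ligand Jag2 from 99.2 ± 9.76 to 0.618 ± 0.235. Guca2a, the peptide guanylin, had 88.3 ± 23.8 and 0.186 ± 0.322 TPM, and the transaminase Gpt 89.7 ± 17.0 and 0.678 ± 0.682. Each of these falls held after median centring.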

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

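The tests of rescaling, trimmed-mean scaling, the other splits, the ratio of cartilage to erythroid transcripts and the header names were chosen only after their results were seen; the others were set before. All patterns were found in these data.

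Transcripts listed without a gene name stayed outside the comparison, and some of them were abundant in ETA sheets. Matched by accession, 1668 such genes had a mean of at least 1 TPM, and limma on these alone called 74 higher and 202 lower. Those with at least 200 TPM in ETA sheets, at least a 2-fold rise and no overlap with the epidermal sheets were Lce1m with a mean of 31231 TPM in ETA sheets against 1559.8 in epidermal sheets, Rnf227 with 3079 against 212, Ube2d3 with 799 against 118, Malat1 with 558 against 101, Il18 with 545 against 65.7, Neat1 with 418 against 60.7, 4930413G21Rik with 384 against 30.6 and 3300005D01Rik with 203 against 15.1. These values are of the unnamed transcripts alone: Lce1m, Il18 and Ube2d3 have named transcripts as well, and on those Ube2d3 (log2 0.26) and Il18 (log2 0.97) were not called. Lce1m belongs to the late cornified envelope family and Il18 is a cytokine related to Il1a. Malat1 and Neat1 are noncoding RNAs kept in the nucleus.

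The first pattern is that 86.3% of the called genes were lower in ETA sheets. With values rescaled without the 100 most abundant genes 78.4% of the calls then made were lower, which argues against the share of those genes as the whole cause. The share of lower calls was at least 85.3% in each of 3 classes of genes by transcript length and at least 83.5% in each of 3 by GC content, and 68.9% among genes with a mean of at least 50 TPM, which argues against length, GC content or the loss of rare transcripts in shallow libraries as the whole cause. With trimmed-mean scaling 55.2% of calls were lower, but it sets the middle of the values itself, so a fixed total shared with very abundant transcripts cannot be told apart from a true loss of most transcripts, and the layers the design names remain untested as a biological explanation. Of the 10 splits of the 6 libraries 1, the real one, gave 8613 called genes and the highest other gave 0; so few splits cannot give a share under 0.05.

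The second pattern is the rise of blood, dermal and cartilage transcripts in ETA sheets, which the toxin should peel off without dermis. The ratio of cartilage to erythroid TPM varied 82.4-fold between the 3 ETA sheet libraries, which argues against 1 tissue carried over with all of them in one proportion. Of 24 further cartilage genes 14 passed the filter, and 92.9% of these were highest in ETA sheet replicates 1 and 2. Cytl1 had 323 and 388 TPM there, 36.4 in replicate 3 and at most 49.9 in epidermal sheets. No chance level can be set beside this share. The 2 replicates were picked because the cartilage list was high in them, and cartilage genes move together. Some, such as Clec3a with 4.65 and 5.28 TPM there, passed the filter only through these 2 libraries. Ear cartilage in those 2 sheets is a candidate source. Of 12 further red cell genes 8.33% rose, below the bound set beforehand, but that bound was ill-chosen: all 12 had at least 1 TPM in epidermal sheets, which hides a small addition, and the other 12 lay under the filter. Red cell RNA therefore stays open, as does expression of globin in the upper epidermis, which was not tested; Alas2, the erythroid enzyme of haem synthesis, was 0.594%, 0.355% and 0.580% of Hbb-bs in the 3 ETA sheet libraries.

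The last pattern is the disagreement of column headers and titles. Groups by header names gave 0 called genes against 8613 by titles, which argues against the header names as the true groups. In the 2 libraries where header and title are alike, epidermal sheet replicate 1 and ETA sheet replicate 3, Krt5 had 6356 and 32.7 TPM and Lor 4384 and 93145, the order their names give for a basal and a surface marker. No biological explanation was tested.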

How the results depend on the processing

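Of 651 alternative list results 584 were the same, 28 weaker, 26 stronger and 13 reversed, and of 2669 gene results 2541 were the same, 69 weaker, 31 stronger and 28 reversed; the cause was not tested. Trimmed-mean scaling gave 2685 higher and 3310 lower genes, 2113 and 2627 of them by at least 2-fold, and median centring 3405 and 2202, with 2734 and 1592. Groups by the header names gave 0 higher and 0 lower genes, with 0 and 0 by at least 2-fold. A test against a 2-fold change gave 524 higher and 3776 lower genes. With the replicate block 1153 genes were higher and 7221 lower. The labels do not say whether equal numbers mark related libraries. Deviations from the group means correlated at 0.0194, -0.0303 and -0.0445 between equally numbered libraries, which cannot decide it with 3 libraries per group. Lists higher were 2 and lists lower 0 with an estimated correlation, and lists lower were 8 without the filter, 8 with trimmed-mean scaling, 9 with median centring and 18 with fry. The list medians given next, relative to all genes, are those of settings in which the camera direction turned, of lists that did not pass as deposited, with the widest values from leaving out 1 library. Without the filter they were -0.48 for desmosome, -0.81 for transcription factors, 0.0398 for ion channels, -0.65 for immediate early genes and -0.25 for the clock. The desmosome list had 0.0469 with library weights, 0.14 without epidermal sheet replicate 1, 0.0234 without ETA sheet replicate 1, 0.22 without ETA sheet replicate 2 and 0.11 without ETA sheet replicates 1 and 2. Transcription factors had -0.28 without ETA sheet replicate 1, immediate early genes -0.10 without ETA sheet replicates 1 and 2, and heat shock genes 0.82 with trimmed-mean scaling and 0.57 with median centring. Log2 fold changes that turned with trimmed-mean scaling and median centring were 0.12 and 0.34 for Tgm5, 0.12 and 0.27 for Perp, 0.82 and 0.97 for Junb, 0.63 and 0.79 for Krt10, 0.27 and 0.42 for Krt2, 0.0827 and 0.24 for Dsg1a and 0.81 and 0.97 for Cldn1. With median centring alone they were 0.10 for Krt1, 0.25 for Tjp1 and 0.35 for Tnni2. In that setting the median of all tested genes was 0.157. Rescaled without the 100 most abundant genes, Junb had 0.0179 and Cldn1 0.0178. Tjp1 had 0.15 with the largest transcript, Tnni2 0.21 without ETA sheet replicates 1 and 2, and Klf4 -0.0118 without ETA sheet replicate 3 and 0.26 without replicate 2. Ivl had -0.0866 with library weights, -0.12 without ETA sheet replicate 1, 0.36 without replicate 3 and -0.15 without ETA sheet replicates 1 and 2. Trpv3 had -0.0417 with a pseudocount of 5, -0.57 without epidermal sheet replicate 1, 0.41 without epidermal sheet replicate 3 and -0.17 without ETA sheet replicate 3. The log2 ratio of the Merkel cell sum was 0.0523 as a mean of log2 values, 2.05 without epidermal sheet replicate 3, 0.13 without ETA sheet replicate 1 and 0.10 without ETA sheet replicate 3.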

Other observations

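The gene families below were chosen after the data were seen, so all counts and p-values are descriptions of these libraries. Ligands of the interleukin-1 family, cytokines of barrier tissues, rose in ETA sheets: 7 of 10 rose and 1 fell, and 9 were higher after median centring (camera adjusted p = 1.25e-07 over 15 families; adjusted p = 0.0671 with an estimated correlation). Beyond Il1a and Il1f8, Il1f9 rose from 87.7 ± 12.3 to 459.8 ± 94.9 TPM, Il1f5 from 175 ± 30.4 to 572 ± 115 and Il1f10 from 118 ± 10.5 to 375 ± 58.4 (SD, n = 3). The member that fell was Il33. Il1a, Il1b, Il1f6, Il1f8, Il1f9 and Il33 are also in the list of alarmins, as are Defb3, Defb4 and Defb14 of the beta-defensins. Neither family therefore gives support apart from that list. Of 7 beta-defensins 3 rose and 1 fell (camera adjusted p = 0.00703; adjusted p = 0.246 with an estimated correlation), the latter being Defb6, from 1046.5 ± 80.9 to 35.8 ± 5.73 TPM, a fall that held after median centring (log2 -3.35) beside the rise of Defb14.

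Keratins divided by member: of 40 tested 4 rose and 17 fell as deposited, and 7 rose and 6 fell after median centring (camera adjusted p = 0.239). Krt23 rose from 249.7 ± 25.3 to 1579.8 ± 244 TPM, Krt80 from 525 ± 54.8 to 2679 ± 312 and Krt78 from 69.6 ± 2.42 to 156 ± 26.5, while Krt15 fell from 2263 ± 62.1 to 49.2 ± 31.3. Subunits of the vacuolar proton pump, which acidifies lysosomes, numbered 18: 2 rose and 7 fell as deposited, but 12 were higher and 1 lower after median centring (camera adjusted p = 0.239). Atp6v0a2 rose 3.41-fold under the deposited scaling. Mitochondrial ribosomal proteins fell in 73 of 77 cases and rose in 1 (camera adjusted p = 0.000482; adjusted p = 0.830 with an estimated correlation), with 25 lower and 8 higher after median centring. Collagens numbered 27, of which 12 rose and 8 fell (camera adjusted p = 0.000162; adjusted p = 0.749 with an estimated correlation), and some of these are also in the fibroblast and cartilage lists. The remaining families had camera adjusted p of 0.118 for glutathione transferases, 0.155 for proteasome subunits, 0.239 for translation initiation factors and aldehyde dehydrogenases, 0.241 for ubiquitin-conjugating enzymes, 0.388 for the Skint family and 0.754 for S100 proteins, clade B serpins and annexins.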
